A study of Mus musculus with 12 samples.

How the data were processed

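The series holds 12 RNA-seq libraries of mouse prostate organoids, 6 labelled SPOPmut and 6 labelled SPOPwt. Per the labels' protocols, prostate cells were grown in Matrigel with EGF, and Cre recombinase fused to an estrogen receptor domain was switched on by a tamoxifen metabolite. In model A this recombinase was delivered by virus, and in model B it came from a transgene under the Tmprss2 gene. Cells were then sorted by GFP, or passed through the sorter without selection as controls. The protocols state that 5 pairs came from model A and 1 pair from model B, and no library's own label says which model it is. Libraries were made with the TruSeq RNA kit, version 2, which does not mark strand, and sequenced as paired-end reads on an Illumina HiSeq instrument.

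The deposited values are RPKM (read number relative to transcript length and library depth) for 43243 gene names, 1 file per library, as the file names state. The submitters' processing notes name STAR 2.4.0j and the builds mm10 and GRCm38. The counting program, the annotation and the treatment of reads that map to several places are not given in the sources used here. Gene length and depth were divided out by the authors, and no scaling between libraries beyond that is recorded. RPKM is relative to the other genes, so a few abundant genes can shift it: the 10 most abundant genes took 7.99 to 14.7% of the summed RPKM per library, and the sums ran from 316623 to 358260.

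Depth was estimated from the spacing of low values with exon lengths from GENCODE M21, in which 91.2% of the gene names (39432) were found. It was 28270000 to 40980000 reads per library, a ratio of 1.45, and the step may be a read pair or a single read. Of values of up to 20 approximate reads, 33.0 to 35.7% lay at a multiple of 0.5 reads, within 0.04 of that step, where 8% would by chance. Whole reads were therefore not recovered for nearly all genes, no count test was run, and no counting interval is given. Coordinates are those of the same annotation on GRCm38. Libraries of the same group were compared for duplicates by a chi-square of approximate reads per gene. The lowest median was 1.294, between the S1 and S2 controls, against 0.455 from sampling alone, so none were merged. Next came the S1 and S2 mutants at 2.242, and all other medians were at least 8.568.

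All computing was in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Values were transformed to log2(RPKM + 1), so a difference understates the change of genes of low level. Genes at an RPKM of at least 1 in at least 6 of the 12 libraries were kept (13600). limma fitted pair and genotype, with a trended and robust variance prior, and two-sided p-values were adjusted by Benjamini-Hochberg and called under 0.05. The groups, the tests, the gene lists, the rule for named genes and most of the other settings were fixed before the data were examined.

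Pairing was taken from the labels: the protocols speak of pairs of mutant and control, and both groups are numbered S0 to S5. Samples of the same number deviated from their group means together in 5 pairs, with correlations across genes of 0.753 (S1), 0.888 (S2), 0.946 (S3), 0.862 (S4) and 0.954 (S5), but hardly in S0 (0.0602). The values of S0 thus give no support of their own to its pairing. Such correlations also arise between libraries of like cells, so they do not show that the own partner is the closest. Compared directly, the mutants of S2 to S5 correlated best with their own control. The S1 mutant correlated better with the S2 control (0.9892) than with its own (0.9873), as did the S0 mutant (0.967 against 0.9435). Index sequences in the labels are shared by S1 and S3 and by S2 and S4 within a group, and no other batch is labelled.

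Gene lists, 28 in all, were tested where at least 5 members were kept, with camera at a preset correlation of 0.01, camera with an estimated correlation, fry, and an exact two-sided sign-flip test of the list mean over the 6 pairs. fry asks whether the genes of a list move on balance to one side and does not compare them with other genes. Named genes were Spop; the 12 genes of largest change in each direction among those past the threshold with 1 direction in all pairs, or, where none passed, the 5 of smallest p in each direction; the passing members of each list, or the 2 of smallest p; and the most abundant tested member of each cell type list. A gene that this rule names is not reported here. Gene models without a name were skipped among the genes of smallest p. Krt5, Krt14, Krt18, Epcam, Col1a1, Vim and Mki67 were picked from the fixed lists or as textbook markers after their values were seen. So were the genes called only with pair weights, the histone genes other than Hist1h2bh, and Ddx3y, Xist, Hoxd13 and Cdkn2a.

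The fit was tested on simulated data of the same 13600 genes and 6 pairs with 50 genes changed at each fold. It recovered 74% of genes changed 1.5-fold, 94% at 2-fold, 98% at 4-fold and 100% at 8-fold, none in the wrong direction, with 10 false calls, and called 0 genes when none were changed. The simulation assumed independent genes and equal spread in every pair, which the real pairs do not have. For lists, camera detected a list moved on purpose in the same simulation, and 3 of 200 unmoved lists fell under 0.05. These lists held random independent genes, so this does not extend to lists whose genes move together.

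The alternatives were no block for pair, pseudocounts of 0.1 and 0.5, no filter and an RPKM filter of 5, a trimmed mean of log ratios and quantile normalization, a plain variance prior, averaging of libraries with shared indexes, other thresholds and leaving out each pair. Pair weights, leaving out pairs S0 and S5 together, and the sign-flip test of lists were added after the data were seen.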

Results

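RNA was sequenced from mouse prostate organoids, Matrigel cultures grown from digested prostate tissue, with a mutant SPOP (SPOPmut) or without it (SPOPwt). SPOP is the substrate-binding subunit of a cullin-based ubiquitin ligase, and the comparison asks which genes differ between SPOPmut and control organoids. By the protocols, cells were sorted by GFP while controls passed the sorter without selection. An effect of the mutant and an effect of that selection therefore cannot be told apart. There were 6 SPOPmut and 6 SPOPwt libraries, numbered S0 to S5 in each group and treated as 6 pairs. The estimated depth was 28270000 to 40980000 reads per library, with a mean of 33750000 ± 3230000 in SPOPmut and 37890000 ± 1870000 in SPOPwt (SD, n = 6). At this depth an RPKM of 1 in a transcript of 2 kb corresponded to 56.5 to 82.0 reads, and 13012 to 13885 genes stood at an RPKM of 1 or more per library. The labels' protocols give 5 pairs from an organoid model with virally delivered Cre and 1 pair from a model with transgenic Cre. They do not say that the 5 pairs came from separate cultures or animals, so the p-values measure only the spread between these samples, which among the 5 may be technical.

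Spop itself stood at 51.4 ± 3.66 RPKM in SPOPmut and 46.0 ± 4.18 RPKM in SPOPwt (SD, n = 6). It was higher in the mutant in 6 of 6 pairs, by 0.16 on the log2(RPKM + 1) scale (SE 0.067, 95% confidence interval 0.0049 to 0.31), or 1.12-fold. The smallest difference was 0.035 in pair S0 and the largest 0.27 in pair S5. An exact two-sided sign-flip test over the pairs gave p = 0.03125, the smallest that 6 pairs allow, while limma gave an adjusted p of 0.886 over all genes tested. Spop lies on chromosome 11 at 95414080 to 95493406 (plus strand, GRCm38). The mutant is a transgene in the Rosa26 locus, so Spop values may hold reads of both the endogenous gene and the transgene.

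**Figure D1:**
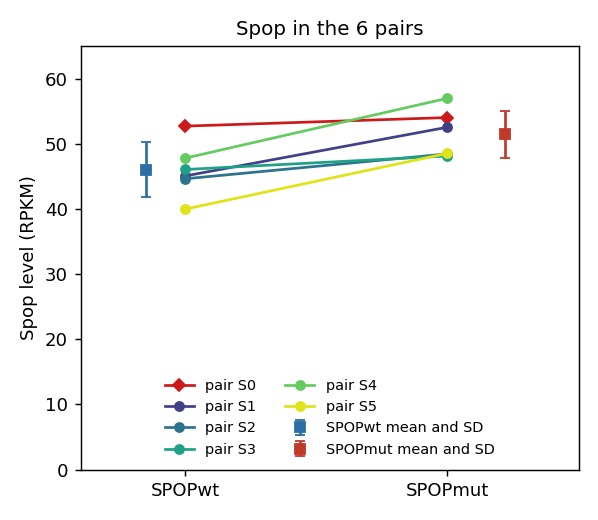
Spop level in RPKM (vertical axis) in SPOPwt and SPOPmut; each line joins the libraries of a pair, and squares with bars give the mean and SD of 6 libraries. The SPOPmut library is above its SPOPwt partner in 6 of 6 pairs, by 0.035 to 0.27 on the log2(RPKM + 1) scale.

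Cell type markers separated pair S5 from the other pairs, in mutant and control alike. Keratin 5 and keratin 14, intermediate filament proteins of basal epithelial cells, stood at 1194 to 1705 RPKM (Krt5) and 656 to 1051 RPKM (Krt14) in the S5 libraries, and at no more than 0.24 and 0.20 RPKM in the 10 libraries of S0 to S4. Epcam, an epithelial adhesion protein, stood at 88.6 to 96.3 RPKM in S5 and at no more than 1.28 RPKM in S0 to S4. The reverse held for Col1a1, a chain of type I collagen (269 to 848 RPKM in S0 to S4, 0.16 to 0.20 in S5), and for Vim, the mesenchymal intermediate filament vimentin (213 to 525 and 0.037 to 0.058 RPKM). Over whole lists, the mean log2(RPKM + 1) of 19 fibroblast and smooth muscle markers was 3.63 to 5.35 in S0 to S4 and 0.57 to 0.69 in S5. That of 24 basal markers was 1.31 to 1.63 against 4.85 to 5.10, and that of 23 luminal markers 1.79 to 2.30 against 4.51 to 4.59. Proliferation genes also varied: Mki67 ranged from 5.70 to 55.0 RPKM in S0 to S4 and from 0.63 to 1.65 RPKM in S5. Immune markers (mean log2 levels of 0.21 to 0.33 over the 12 libraries), endothelial markers (0.20 to 0.62), seminal vesicle markers (0.10 to 0.17) and neuroendocrine markers (0.41 to 0.72) were low throughout. Their most abundant tested members were Cd68 at 3.65 ± 0.72 RPKM, Egfl7 at 1.28 ± 0.22, Tgm4 at 1.37 ± 0.24 and Sox2 at 8.39 ± 2.31 in SPOPmut (SD, n = 6), and none differed from SPOPwt at an adjusted p under 0.05 in limma.

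**Figure D2:**
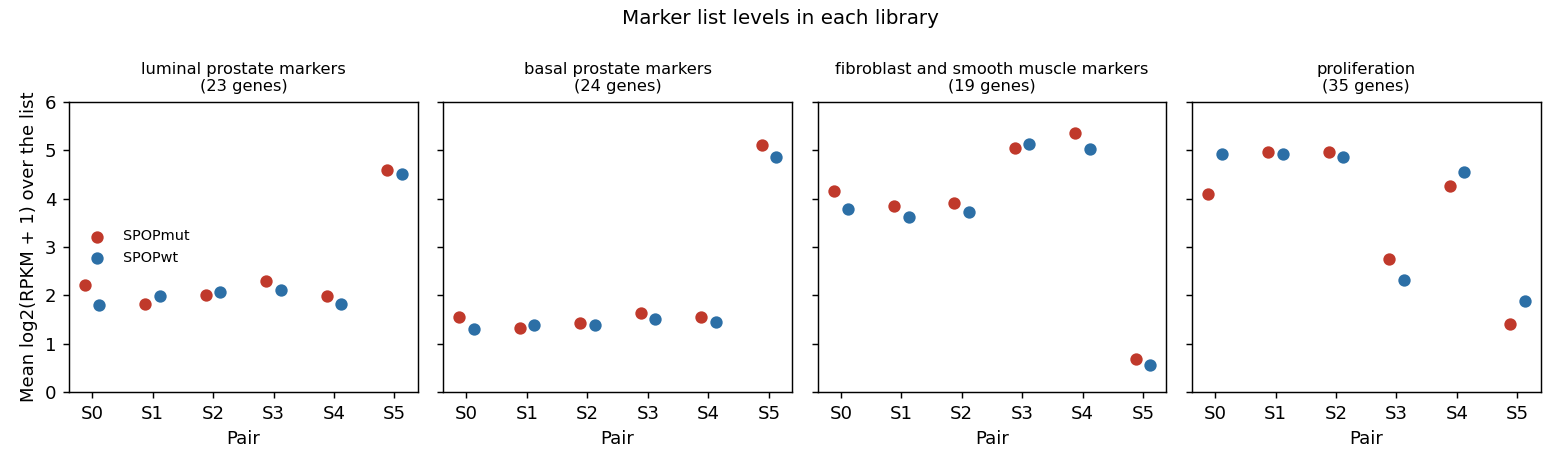
Mean log2(RPKM + 1) of 4 marker lists (vertical axis) in each library, by pair (horizontal axis) and genotype (colour); each point is 1 library. Fibroblast and smooth muscle markers lie at 3.63 to 5.35 in S0 to S4 and at 0.57 to 0.69 in S5, while basal markers lie at 1.31 to 1.63 and 4.85 to 5.10.

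Between SPOPmut and SPOPwt, the smallest p-value belonged to Sulf2, a sulfatase that edits heparan sulfate, at 15.5 ± 6.14 RPKM in SPOPmut and 10.8 ± 4.06 RPKM in SPOPwt (SD, n = 6), a log2 difference of 0.47 (SE 0.060, limma adjusted p = 0.583). Next among the higher genes came the protocadherin Pcdh18 (0.36, SE 0.063), the glycosyltransferase Galnt18 (0.47, SE 0.084), the matrix protein thrombospondin 2 (Thbs2, 0.58, SE 0.11) and the lipid carrier apolipoprotein D (Apod, 0.59, SE 0.11), each higher in 6 of 6 pairs with an adjusted p of 0.769. The lowest p-values among the lower genes were those of Mir5136 (-0.45, SE 0.073), the histone gene Hist1h2bh (-0.70, SE 0.11), Sh3bgrl2 (-0.42, SE 0.079), the surface protein mesothelin (Msln, -0.65, SE 0.12) and choline kinase alpha (Chka, -0.45, SE 0.096). All 5 were lower in 6 of 6 pairs, again with an adjusted p of 0.769. Msln stood at 109 ± 101 RPKM in SPOPmut and 181 ± 174 RPKM in SPOPwt, and Hist1h2bh at 0.94 ± 0.47 and 2.21 ± 1.09 RPKM.

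None of these genes, and none of the 13600 tested, passed an adjusted p under 0.05 in limma: 0 were higher and 0 lower, with 761 at an unadjusted p under 0.05 (520 higher, 241 lower) where 680 are expected by chance. With quantile normalization the split was 473 higher and 353 lower. A single direction in all 6 pairs was seen for 721 genes (493 higher, 228 lower), 5.30% of those tested against 3.125% expected with no effect. Both expectations take the 6 pairs as independent, which is not assured. Across genes, the differences of S1 and S2 correlated by 0.506 and those of S0 and S4 by 0.369, against -0.27 to 0.23 for the other combinations. Weighting the pairs by their residual spread, an alternative chosen after the data were seen, called 7 genes higher and 2 lower at limma adjusted p-values of 0.0258 to 0.0412. The 7 were Aqp1 (0.94), Cldn1 (0.88), Cgref1 (0.55), Lxn (0.43), Sulf2 (0.44), Kctd14 (0.39) and Pcdh18 (0.38), and the 2 were Gm24103 (-0.40) and Mir5136 (-0.55).

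In GRCm38, Sulf2 lies on chromosome 2 at 166073089 to 166155663 and overlaps Ncoa3 on the opposite strand. Pcdh18 lies on chromosome 3 at 49743296 to 49757325, Galnt18 on chromosome 7 at 111471661 to 111779977, Thbs2 on chromosome 17 at 14665500 to 14694235 and Apod on chromosome 16 at 31296192 to 31314808. Mir5136 (chromosome 19, 8888699 to 8888774) lies within Lbhd1 on the opposite strand. The kit does not mark strand, so its reads cannot be told from those of Lbhd1 and its value is uncertain. Hist1h2bh (chromosome 13, 23541714 to 23543392) belongs to a family of near-identical genes that can share reads, and its value is uncertain for that reason. Sh3bgrl2 (chromosome 9, 83548327 to 83638801) and Chka (chromosome 19, 3851773 to 3894369) overlap non-coding genes on the opposite strand, and Msln lies on chromosome 17 at 25748613 to 25754378.

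**Figure D3:**
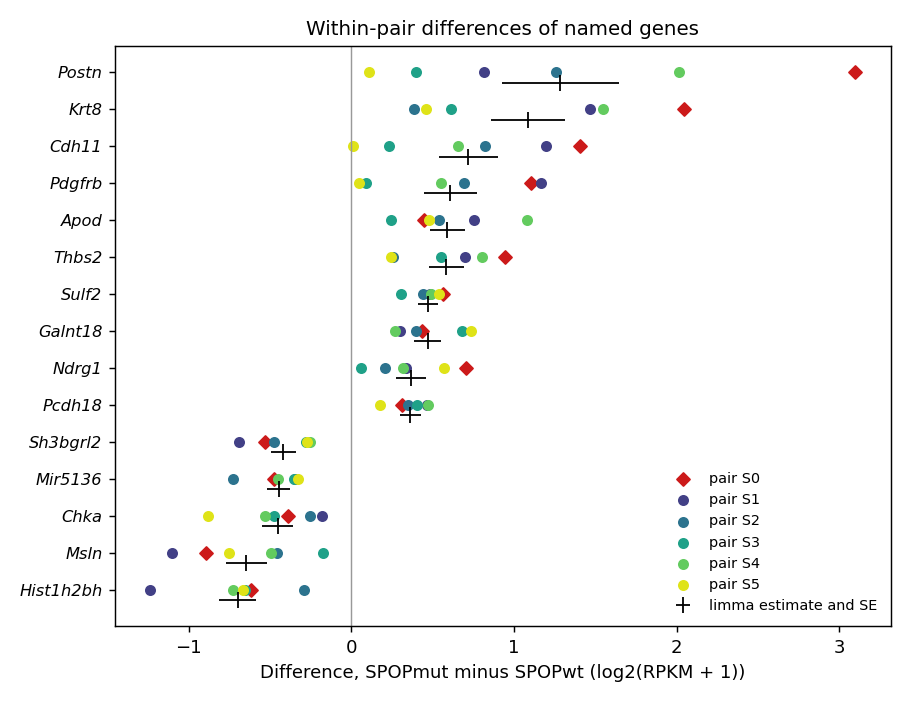
Difference between SPOPmut and SPOPwt on the log2(RPKM + 1) scale (horizontal axis) for the 5 higher and 5 lower genes of smallest p and for 5 members of the gene lists; points are the 6 pairs, and black marks with bars are the limma estimate and SE. Sulf2 lies at 0.30 to 0.56 in the 6 pairs, and Postn at 0.11 to 3.10.

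Among the gene lists, interferon response genes had a mean difference of 0.25 ± 0.31 (SD over 6 pairs), with 26 of the 27 tested members higher on average in SPOPmut, 7 of them in all 6 pairs. The camera test with its preset correlation of 0.01 gave an adjusted p of 4.21e-10 for the list, against an adjusted p = 0.383 with an estimated correlation. The list mean was 0.78 in pair S0, 0.45 in S5 and 0.21 in S4, but 0.0067 in S1, -0.025 in S2 and 0.064 in S3, and without S0 it was 0.14 (camera adjusted p = 0.000269). The interferon call ended without S0 and S5 together (mean 0.064, adjusted p = 0.165) and with pair weights (0.066, adjusted p = 0.253). B2m, the light chain of class I histocompatibility molecules, was higher by 0.37 (SE 0.12) and Ddx58, the RNA sensor RIG-I, by 0.33 (SE 0.11), each in 6 of 6 pairs and each at an adjusted p of 0.881. Fibroblast and smooth muscle markers had a mean of 0.28 ± 0.23, with 11 of 14 members higher, and epithelial mesenchymal transition genes one of 0.19 ± 0.18, with 16 of 25 higher. Each list mean was higher in 5 of 6 pairs and lower in S3 (-0.098 and -0.059). In these lists Pdgfrb, a growth factor receptor of mesenchymal cells, was higher by 0.61 (SE 0.16), the collagen gene Col6a1 by 0.46 (SE 0.14), the mesenchymal cadherin Cdh11 by 0.72 (SE 0.18) and the matrix protein periostin (Postn) by 1.28 (SE 0.36), each in 6 of 6 pairs. S100a4, the most abundant member, was higher by 0.27 (SE 0.11). The camera adjusted p was 0.000103 for the fibroblast list and 0.00021 for the transition list, and for each the adjusted p = 0.383 with an estimated correlation. Without the block for pair neither was called (adjusted p = 0.317 and adjusted p = 0.095). In pair S5, where these markers were near 0, the differences of Cdh11, Pdgfrb and Postn were 0.0083, 0.046 and 0.11.

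FOXO targets were higher in 6 of 6 pairs, with a mean of 0.20 ± 0.33 and 17 of 18 members higher, of which Klf15 was higher by 0.43 (SE 0.14) and the transcription factor Foxo3 by 0.32 (SE 0.11). The mean was 0.87 in pair S0 and no more than 0.10 in any other pair, and without S0 it was 0.064 (camera adjusted p = 0.21). Camera gave an adjusted p of 0.00016, against an adjusted p = 0.425 with an estimated correlation. Androgen receptor targets had a mean of 0.11 ± 0.10 and 17 of 24 members higher, among them Ndrg1 (0.37, SE 0.093, 6 of 6 pairs) and the kinase gene Sgk1 (0.28, SE 0.091, 5 of 6 pairs). Their camera adjusted p was 0.00426, and the adjusted p = 0.383 with an estimated correlation; without S0 the mean was 0.075 (adjusted p = 0.0834). Luminal markers had a mean of 0.14 ± 0.38 over the 11 of 23 members tested (camera adjusted p = 0.0439, and adjusted p = 0.425 with an estimated correlation). The luminal mean was 0.79 in pair S0 but -0.34 in S1 and -0.094 in S2, and without S0 it was 0.013 (adjusted p = 0.792). The luminal call also ended without S3 (adjusted p = 0.115) and without S5 (adjusted p = 0.0752), and the mean was 0.25 without S1. Without the block for pair the adjusted p was 0.327. Their member Krt8, a keratin of luminal cells, was higher by 1.09 (SE 0.23) in 6 of 6 pairs, with an adjusted p of 0.769 over all genes and 0.0141 adjusted over the list alone. It was the only member of the 23 lists tested to pass when adjusted over the list alone. That adjustment treats each list by itself and does not account for the number of lists. Krt8 stood at 1.44 to 21.5 RPKM in S0 to S4 and at 247 to 340 RPKM in S5. Epcam stood at no more than 1.28 RPKM in S0 to S4, so a difference in Krt8 there does not by itself show luminal cells. Krt18, a keratin of the same list, did not follow: its difference was 0.25 (SE 0.33), higher in 3 of 6 pairs and lower in S1, S2 and S3. Another luminal member, the transcription factor Hoxb13, was higher by 0.17 (SE 0.055) and the most abundant, Ly6a, was lower by a log2 difference of -0.18 (SE 0.17). Basal markers had a mean of 0.087 ± 0.17 over the 10 of 24 members tested, with Snai2 at 0.27 (SE 0.084) and the caveolin gene Cav1 at 0.22 (SE 0.082). Krt5 and Krt14 fell below the level filter and were not tested. Unlike them, Cav1 and Snai2 reached up to 299% and 119% of the S5 control level in S0 to S4, so they do not mark basal cells there. For the basal list camera gave an adjusted p of 0.0102, and the adjusted p = 0.383 with an estimated correlation. The basal mean was 0.046 without S0 (adjusted p = 0.0863) and 0.17 without S1, and without the block for pair the adjusted p was 0.0939.

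For p53 targets the mean was 0.14 ± 0.24 with 20 of 24 members higher, among them the death receptor gene Fas (0.60, SE 0.24) and Phlda3 (0.22, SE 0.091). The Fas difference was 1.74 in S0, 1.23 in S5 and -0.11 to 0.56 in the other pairs. Inflammatory and NF-kB targets had a mean of 0.23 ± 0.75, made of 1.72 in pair S0 and -0.30 to 0.14 in the others. Relb was higher by 0.34 (SE 0.12) and the chemokine gene Ccl20 by 0.36 (SE 0.16). Both were largest in S0, at 0.88 and 1.16, against -0.065 to 0.51 and -0.023 to 0.68 in the other pairs. Camera gave adjusted p-values of 0.0018 and 0.00427 for these lists, against adjusted p = 0.425 and adjusted p = 0.572 with an estimated correlation. Without S0 the p53 mean was 0.075 (adjusted p = 0.0824) and the inflammatory mean -0.065 (adjusted p = 0.18), and without S5 the p53 call also ended (adjusted p = 0.116). The p53 mean was 0.22 without S1, and the inflammatory mean 0.35 without S3 or without S4. Without S0 and S5 together the inflammatory list was called lower (mean -0.12, adjusted p = 0.00463).

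On the lower side, the mean difference of amino acid synthesis and ATF4 targets was -0.16 ± 0.23, with 20 of 25 members lower; the stress-induced transcription factors Atf5 (-0.47, SE 0.13) and Ddit3 (-0.25, SE 0.067) were lower in 5 and 6 of 6 pairs. Ribosome biogenesis and MYC targets had a mean of -0.23 ± 0.56 and 26 of 26 members with a lower mean, including Myc (-0.39, SE 0.11) and the nucleolar gene Nop56 (-0.36, SE 0.16). The ribosome mean was -1.30 in pair S0 and higher in the mutant in 3 of 6 pairs (0.25 in S1, 0.11 in S2 and 0.012 in S5), and without S0 it was -0.011 (adjusted p = 0.433). Proliferation genes had a mean of -0.17 ± 0.45 with 35 of 35 members lower on average, including the cell cycle genes E2f1 (-0.33, SE 0.13) and Ccne1 (-0.45, SE 0.23). Pair S0 was lowest for both, at -0.96 for E2f1 and -1.71 for Ccne1, against -0.56 to 0.053 and -0.71 to 0.20 in the other pairs. Pair by pair, however, the proliferation mean was -0.82 in S0, -0.48 in S5, -0.29 in S4, 0.048 in S1, 0.10 in S2 and 0.43 in S3; it was -0.039 without S0 (adjusted p = 0.143), -0.29 without S3 and -0.11 without S5. The amino acid mean was -0.082 without S3 (adjusted p = 0.0058). Camera gave adjusted p-values of 1.41e-06 (amino acid), 2.94e-06 (ribosome) and 4.93e-06 (proliferation), against adjusted p = 0.383, adjusted p = 0.425 and adjusted p = 0.501 with an estimated correlation.

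Homologous recombination and Fanconi genes had a mean of -0.11 ± 0.16 with 22 of 27 members lower, among them Rad51c (-0.20, SE 0.061) and Palb2 (-0.21, SE 0.079), both near 1 RPKM; without S0 the mean was -0.054 (adjusted p = 0.0104), and with pair weights, -0.029, the list was not called (adjusted p = 0.0507). Glycolysis and hypoxia genes were lower in 6 of 6 pairs by a small mean of -0.064 ± 0.059, with the mitochondrial kinase gene Pdk1 at -0.18 (SE 0.059) and Pfkfb4 at 0.18 (SE 0.059). Cholesterol synthesis genes had a mean of -0.13 ± 0.62, which was -1.26 in pair S0 and 0.57 in pair S1, and 24 of 25 members had a lower mean, such as Acat2 (-0.33, SE 0.26) and Tm7sf2 (-0.14, SE 0.12). Camera gave adjusted p-values of 1.07e-05 (recombination), 0.00426 (glycolysis) and 0.0105 (cholesterol), against adjusted p = 0.425, adjusted p = 0.383 and adjusted p = 0.645 with an estimated correlation. Without the block for pair the glycolysis list was not called (adjusted p = 0.0939). The cholesterol mean was -0.27 without S1 and -0.20 without S2, but 0.098 without S0, where it was called higher (camera adjusted p = 0.0325).

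Genes of SPOP substrates, whose proteins SPOP marks for degradation, had a mean of -0.026 ± 0.066 over 21 members (camera adjusted p = 0.268), although Brd2 (-0.24, SE 0.070) and Ddit3 were lower in 6 of 6 pairs. The list mean was higher in 4 of 6 pairs and lower in S0 (-0.13) and S4 (-0.086), and without S0 it was -0.0047. In the PI3K and mTOR list (mean 0.041 ± 0.056, median -0.0047, camera adjusted p = 0.372), Pik3r1, a regulatory subunit of the kinase, was higher in 4 of 6 pairs by 0.28 (SE 0.098, limma adjusted p = 0.881). The remaining lists that were not called were Notch (mean 0.069, with Notch2 at 0.23 and Notch1 at 0.18), fatty acid synthesis (-0.067, with Fasn at -0.21 and Gpam at -0.10) and Wnt targets (0.060, with Myc at -0.39 and Fzd7 at 0.26). So were immediate early and heat shock genes (0.060, with Hspa1a at 0.16, Zfp36 at 0.30 and Hspa8 at -0.15), NRF2 targets (0.013, median -0.028, with Gstm1 at 0.45 and Gstm2 at 0.20) and hedgehog targets (0.0053, median -0.0076, with Ccnd1 at -0.17 and Hhat at 0.11). Their camera adjusted p-values ran from 0.102 for Notch and 0.115 for fatty acid synthesis to 0.902 for hedgehog. Leaving out a pair gave calls for Notch (0.11 without S1, adjusted p = 0.0479, and 0.11 without S3, adjusted p = 0.0338) and for fatty acid synthesis (-0.13 without S1, adjusted p = 0.0146, and -0.12 without S2, adjusted p = 0.0142). Immediate early genes were called higher without S3 (0.12, adjusted p = 0.0357) or without S4 (0.13, adjusted p = 0.036), and lower without S0 and S5 together (-0.11, adjusted p = 0.00164). With libraries of the same index averaged, fatty acid synthesis was called lower (-0.13, adjusted p = 0.0222) and immediate early genes higher (0.15, adjusted p = 0.0202). With no filter on low values, all 28 lists were tested and 17 were called, among them Wnt targets as higher (0.067 over 20 members, adjusted p = 0.0263). Mean and median differ in sign for the PI3K, NRF2 and hedgehog lists, and camera's direction for NRF2 was down. The lists of squamous differentiation, neuroendocrine, immune, endothelial and seminal vesicle genes had fewer than 5 tested members at the main filter and no list test there. Without the filter these lists were tested too, and the 17 calls reach into this group, with no value given by list. Their named members were Sprr1a (-1.01, SE 0.38), Sprr2a1 (-0.58, SE 0.21, lower in 5 of 6 pairs but higher in S5), Sox2 (0.15), Eno2 (0.15), Cd68 (0.092), Csf1r (-0.042), Egfl7 (-0.14) and Tgm4 (-0.096), none past an adjusted p under 0.05.

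Of the 23 lists tested, camera with the preset correlation called 15 (9 higher, 6 lower), camera with an estimated correlation 0, and fry 0 after adjustment (3 at an unadjusted p under 0.05). Those 3 were the androgen receptor, fibroblast and mesenchymal transition lists. The estimated correlation had a median of 0.255 over the lists, and was 0.933 for cholesterol synthesis, 0.867 for proliferation, 0.81 for ribosome biogenesis and 0.596 for interferon response. The preset of 0.01 lies far below these, so its p-values are too small for such lists. The estimates were lower for androgen receptor targets (0.0278), mesenchymal transition (0.0844) and glycolysis (0.0854). For these lists too, camera with the estimated correlation gave an adjusted p of 0.383. The exact sign-flip test over pairs also called 0 after adjustment, with 2 (FOXO targets and glycolysis) at an unadjusted p of 0.03125. That test can hardly call a list with 6 pairs, since at least 15 of the 23 lists would have to reach this smallest p for any to pass. Without pair S0, 7 of the 23 lists were called: 6 of the 15 in the same direction, cholesterol synthesis in the other direction (mean 0.098, adjusted p = 0.0325), and 8 of the 15 no longer. With pair weights, 4 of the 15 kept their call: the amino acid, glycolysis, mesenchymal transition and fibroblast lists. Without S0 and S5 together these 4 and the recombination list kept theirs.

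**Figure D4:**
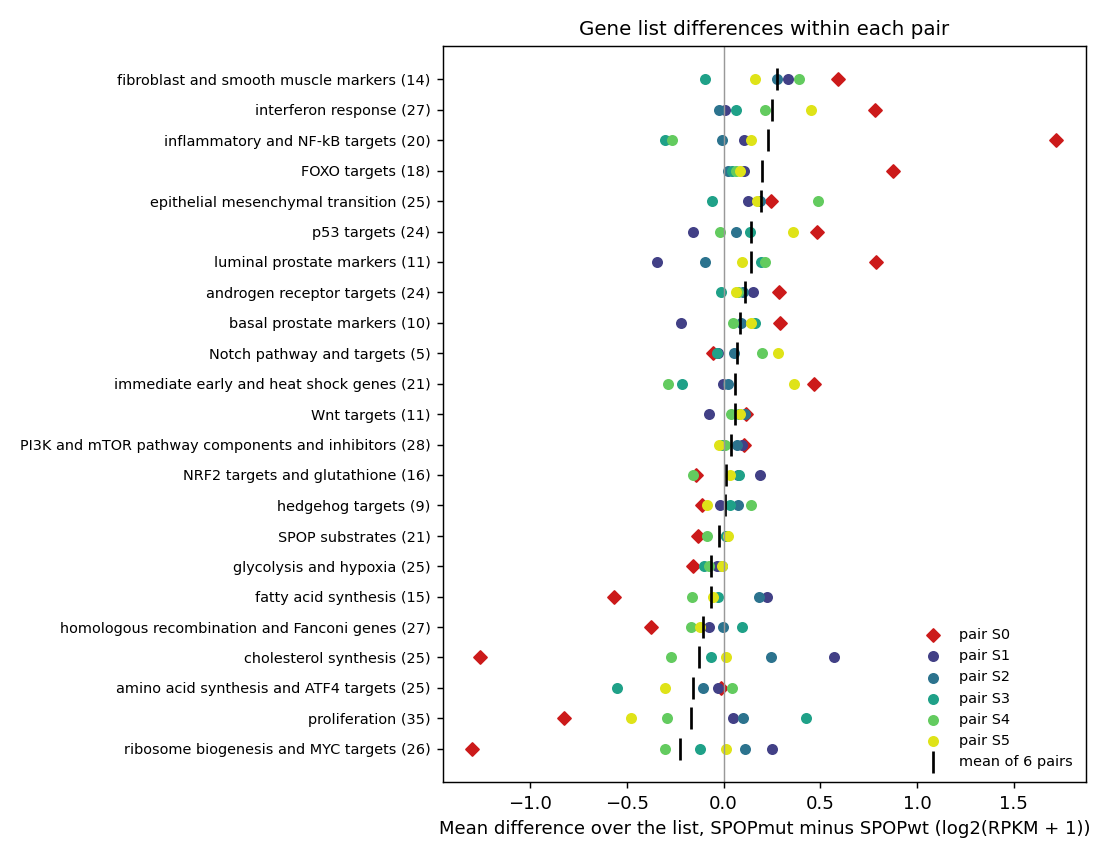
Mean difference between SPOPmut and SPOPwt over each gene list on the log2(RPKM + 1) scale (horizontal axis), with the number of tested members in parentheses; points are the 6 pairs, red diamonds are pair S0, and black bars are the mean of 6 pairs. Pair S0 lies at 1.72 for inflammatory targets, 0.87 for FOXO targets, -1.26 for cholesterol synthesis and -1.30 for ribosome biogenesis.

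The pairs differed in how far mutant and control lay apart. The SD of the gene differences was 0.56 in S0 and 0.16 to 0.30 in the other pairs, and 1001 genes differed more than 2-fold within S0 against 10 in S2, 28 in S3, 58 in S4, 83 in S5 and 91 in S1.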

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

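Dixon's outlier test was applied to 112 sets of 6 values, and 16 had a highest or lowest value set apart by a larger share of the range than the 95% critical value, where chance gives about 5%. Of the 16, 7 concerned pair S0 and 6 pair S5. Tests on epithelial dilution, the organoid models, gene length and an exchanged library were chosen only after the result was seen.

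Pair S5 stood apart in its marker levels. The gap of its mutant to the nearest library took 0.83 of the range for luminal, 0.917 for basal and 0.679 for fibroblast markers, and that of its control 0.883, 0.942 and 0.671. Epithelial cells merely diluted by other cells in S0 to S4 would keep their abundant transcripts. The 27 luminal and basal markers at 20 RPKM or more in the S5 control were compared with that same library. Their median in a library of S0 to S4 reached at most 2.05% of the S5 control, which argues against a substantial share of epithelial cells like those of S5. Single markers varied, from at most 0.0202% for Krt5 to 46.5% for Cd24a, and Cav1 (299%) and Snai2 (119%) exceeded the S5 control. Different scaling of the files is argued against by a median log2 ratio of all tested genes of only 0.0707. A candidate explanation, as a hypothesis, is that S0 to S4 hold mainly cells of mesenchymal type and S5 epithelial cells, and the GFP sort is not described as a selection of cell type; only 3 to 4 of the 19 fibroblast markers reached an RPKM of 1 in S5. Whether the split follows the organoid models cannot be told apart, since 0 libraries carry a label of their model.

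Pair S0 had the widest difference between mutant and control, and the gap of its SD of gene differences took 0.665 of the range over the pairs. Correcting for gene length left an SD of 0.56 against at most 0.296 elsewhere, which argues against a length or integrity bias as the whole cause. An exchange with another pair's mutant would need a partner out of place, and 0 other mutants lay closer to the S0 control than to their own; a single wrong label stays open. Across genes, which are not independent replicates, the S0 differences correlated by r = 0.659 with the difference of the S3 control from the S1 and S2 controls, which differ in Mki67, and those of the other pairs by -0.21 to 0.35. The S3 control also differed from the S1 and S2 controls in other genes, such as Postn (145 RPKM against 2.43 and 3.47) and B2m (359 against 86.5 and 93.5). Growth state may thus contribute to the S0 difference, but this correlation cannot tell it from other differences among these controls. An effect of genotype that appears in S0 alone stays open and untested.

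The same pair set apart the FOXO list (0.906 of the range, difference 0.87), the inflammatory list (0.781, 1.72), the ribosome biogenesis list (0.644, -1.30), Nop56 (0.74, -1.25), Eno2 (0.733, 1.60) and Sprr1a (0.632, -3.24). Pair S2 was lowest for Mir5136 (0.633 of the range, difference -0.73) and pair S4 for Notch1 (0.632, -0.26). The S3 mutant was highest for endothelial markers (0.792 of the range, mean log2 level 0.62).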

How the results depend on the processing

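Counts of called genes were 0 higher and 0 lower under every alternative except pair weights, chosen after the data were seen, which gave 7 and 2; its weights ran from 4.59 (S2) to 0.161 (S0). The smallest adjusted p was 0.0258 with pair weights, 0.104 without S0 and S5 together, 0.199 without S0, and up to 1 elsewhere. Over its alternatives the adjusted p of Sulf2 ran from 0.0258 to 1. Genes at an unadjusted p under 0.05 numbered 761, but 29 with no replicate block, 1467 unfiltered, 428 at an RPKM filter of 5, 393 with shared indexes averaged, 2078 with pair weights and 1288 without S0 and S5. With no replicate block for the pairing, 10 lists were called and Spop kept its difference of 0.16 (adjusted p = 1); the block changed no gene call. The Spop difference was 0.14 to 0.19 under all settings. Called lists numbered 15, against 0 with an estimated correlation, 0 with the sign-flip test (nearly fixed by 6 pairs), 4 with pair weights, 8 without S0 and S5, and 7 to 17 leaving out each pair, 7 being without S0. Leaving out a single library was not run, since under the block it equals leaving out its pair. The cause was not tested for any of these changes or reversals.

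Leaving out each pair, list means crossed 0 for hedgehog (-0.022 to 0.029), NRF2 (-0.021 to 0.045), cholesterol (-0.27 to 0.098), fatty acid (-0.13 to 0.032), inflammatory (-0.065 to 0.35) and immediate early genes (-0.022 to 0.13), and so did Eno2 (-0.14 to 0.25), Cd68 (-0.021 to 0.17) and Csf1r (-0.091 to 0.019). Others came near 0 without crossing it: Zfp36 (0.035 to 0.41), Hspa8 (-0.26 to -0.0050), Acat2 (-0.51 to -0.060) and Tm7sf2 (-0.23 to -0.053). At an RPKM filter of 5 hedgehog was -0.026 and NRF2 -0.0040; with shared indexes averaged they were -0.021 and -0.0039, and with trimmed mean scaling hedgehog was -0.00045. Pair weights reversed SPOP substrates (0.00023), luminal (-0.011), cholesterol (0.13), fatty acid (0.081), proliferation (0.053), inflammatory (-0.038), ribosome (0.0046) and immediate early lists (-0.033), Acat2 (0.054), Tm7sf2 (0.0089), Eno2 (-0.20) and Hspa8 (0.095). Without S0 and S5 the reversed values were cholesterol 0.12, inflammatory -0.12 and immediate early -0.11, called in that direction (adjusted p = 0.0476, 0.00463 and 0.00164), and, not called, luminal -0.0069, fatty acid 0.054, proliferation 0.071, Acat2 0.082, Tm7sf2 0.0045, Zfp36 -0.098, Eno2 -0.22, Cd68 -0.0042 and Hspa8 0.096. Of 1101 alternative values of named genes, 1085 kept direction and side of the threshold. Scaling moved the median of all genes by less than 0.01. Depth limits the low genes, since an RPKM of 1 in 2 kb rests on 56.5 to 82.0 reads.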

Other observations

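Pair S5 also differed from S0 to S4 in other genes. The Y-linked gene Ddx3y stood at 12.7 to 19.2 RPKM in the 10 libraries of S0 to S4 and at 0.047 to 0.089 RPKM in S5, while Xist, expressed from the inactive X chromosome, was at no more than 0.10 RPKM in any library. The posterior homeobox gene Hoxd13 was at 20.4 to 24.96 RPKM in S5 and at no more than 0.084 RPKM in S0 to S4, while Hoxb13, a member of the luminal list, ran opposite to that list at 4.43 to 5.04 and 10.4 to 29.9 RPKM. The cell cycle inhibitor Cdkn2a was at 3.21 to 3.45 RPKM in S5 and at no more than 0.010 RPKM elsewhere.

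The histone genes below were grouped, and their tests chosen, after Hist1h2bh had been seen, and no histone gene passed (lowest limma adjusted p = 0.769). The mean of 12 tested histone genes with names in Hist1h or Hist2h, 7 of them of the H2B family, was -0.25 ± 0.19 (SD over 6 pairs). They were grouped by name alone, and whether each is expressed only during DNA replication was not tested. Hist1h2bc, at 25.4 ± 8.03 RPKM in SPOPmut and 37.9 ± 14.4 in SPOPwt, and Hist1h2bg were lower in 6 of 6 pairs along with Hist1h2bh. So were Hist1h4i (-0.27) and Hist1h1c (-0.18), which are not of the H2B family. Hist2h2aa1 (0.065), Hist2h2be (-0.0050) and Hist2h3c1 (-0.068) did not follow, being lower in 1, 3 and 3 pairs. Without Hist1h2bc, Hist1h2bg and Hist1h2bh, the mean of the other 9 was -0.14 ± 0.14, lower in 5 of 6 pairs (exact sign-flip p = 0.0625). Lower proliferation is argued against in pairs S1 and S2, with histone medians of -0.44 and -0.25 and proliferation medians of 0.025 and 0.096. These pairs may not be separate observations, since their differences correlated by 0.506 across genes. In S3 the medians were -0.070 and 0.47, and in S0, S4 and S5 both were below 0. Weaker recovery of RNA without a poly(A) tail cannot be told apart: the median of 7 such RNAs was below 0 in 2 pairs and at or above 0 in 4, but 2 of the 7 reach a mean RPKM of 1, so genes near 0 fix that median, and this requirement was added after a first reading had counted the test against the explanation. Reads shared between histone paralogs may also contribute.

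Swapping the genotype labels within pairs gives 32 distinct splits. In 5 of them, the real one included, at least 761 genes stood at an unadjusted p under 0.05, and the highest other count was 1470, with S1, S2 and S3 swapped. For a single direction in all 6 pairs the real count was 721 and the highest other 1313, again with 5 of 32 splits as large. Chance cannot be excluded for these 2 counts. Genes past the adjusted threshold numbered 0 in the real split and 0 at most in any other, so 32 of 32 are as large by construction and the swaps decide nothing there.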
